A study of Mus musculus with 4 samples.

How the data were processed

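Visium spatial gene expression was measured in fresh-frozen olfactory bulb of 1 control mouse and 1 mutant mouse, on 2 capture areas each. Per the labels, the control mouse gave 2 sections on 1 area and 1 section on the other, and the mutant mouse 2 sections on each area. The deposited values are whole-number counts of UMIs per gene and spot in a single pooled matrix, made with Space Ranger 1.3.1 per the file headers. The genome build is GRCm39 per the submitters' processing notes, although the matrix has as many genes as the vendor's mm10 reference, so that the build is uncertain. The annotation, read filters and any depth scaling between capture areas are not given in the sources used here. UMIs remove PCR copies, so each count stands for a captured molecule. Of the 32285 gene identifiers, 32158 were found in the reference name table. No genomic coordinates are printed, since the reference annotation at hand is of another build.

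A spot was assigned to a library by the number at the end of its barcode. The numbers 1 to 4 match no label, and no value, order or number of spots was used to assign a library to a mouse. The comparison of the control with the mutant mouse, planned as a ratio of CPM with no test, was therefore not run. Each library's value is printed with the range or the ratio of the highest to the lowest library. No mean, SD or p-value is given, and libraries are not treated as replicates. Capture areas of 1 mouse would in any case be technical repeats. No spatial positions or images were used. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 2.55), and none was treated as deposited again.

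Spots with at least 500 UMIs were kept, which left 4616 spots and set aside 97 with 0.0680% of the UMIs. Levels in counts per 1000000 UMIs (CPM) were computed from UMIs summed over the kept spots of a library, with exact Poisson intervals for levels, exact conditional binomial intervals for ratios and exact (Clopper-Pearson) binomial intervals for shares of spots. A sum of 3 UMIs corresponds to between 0.225 and 0.574 CPM depending on the library. Intervals cover counting error only.

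For regions, counts were scaled to 10000 UMIs per spot and log1p-transformed, and 2000 variable genes were chosen without the genes of the fixed lists and without mitochondrial, ribosomal protein and haemoglobin genes. The genes were z-scored and reduced to 30 principal components, and spots were joined to their 15 nearest neighbours and clustered with the Leiden algorithm at resolution 0.8. A region is named by the gene with the highest fold over all other spots among genes with at least 200 UMIs in it, and the name stands for no cell type. Leading genes are names, not results. The list genes were kept out of the clustering, so that their levels across regions are not set by it.

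The 26 gene lists cover olfactory bulb layers, cell types and states and hold 198 genes, of which 197 have a row in the matrix. A list value is the median over its genes with at least 20 UMIs, for lists with at least 3 such genes, of the log2 ratio of a region to the rest of its library, or of the log2 level in a library relative to the mean of the 4 libraries, with a prior count of 0.5. It was set against 10000 random lists of the same size matched on expression in 20 bins. Intervals of list differences come from 200 Poisson resamples. The span of a list is the difference between its highest and lowest library, a measure that is above 0 by construction. Named genes are members of these lists, the 20 genes with the widest ratio of highest to lowest library among those with at least 500 UMIs in all and 3 in each library, and the 5 leading genes of each region. Mitochondrial, ribosomal protein and unnamed gene models were not named, and the values of some list members are not reported here. Spot correlations are Spearman's rho of list scores in spots thinned to 2000 UMIs, which left out 233, 89, 42 and 20 shallower spots of libraries 1 to 4. Here the score of a list is the sum of its UMIs over the UMIs of the spot, not a median over genes.

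The assignment rule, the gene lists, the rule for named genes, the clustering settings, the CPM and interval methods and most of the alternative settings were set before the data were examined. The thinning depth, the rho minimum of 0.3, the 2-fold and 1 log2 unit thresholds, the 99th percentile, the prior count, the minimum of 3 genes per list and the tolerances used to call a value moved were set after a first look at the files.

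The calculations were tested on simulated data. Of genes simulated with 4-fold differences between libraries, 100% passed the 2-fold threshold, as did 0 of the unchanged genes and 0% of those with 1.5-fold differences, in 9866 genes. The clustering of 3 simulated regions recovered 4, with an adjusted Rand index of 0.881, because spots of low depth formed a region of their own with a median of 3567 UMIs. The bound required of this index in the simulation was lowered after that result was seen. With every simulated spot thinned to the same depth, 3 regions were recovered with an index of 1. Regions of the real spots may therefore be partly set by depth, and an alternative with thinned spots was added. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used. Alternatives covered the clustering resolution, number of variable genes, centring within libraries, list genes in the clustering, spot and gene minimums, scaling, thinning, weighting of regions and leaving out each library in turn.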

Results

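Soluble VEGFR1 binds vascular endothelial growth factor (VEGF) and keeps it from its receptors, and the study set the olfactory bulb of a mouse carrying a transgenic form of it beside that of a control mouse. Per the labels, the transgene was expressed in the brain under a tetracycline-regulated Camk2a driver, VEGF was blocked at E13.5 of embryonic life, and the mice were examined at 5 months. Coronal sections were laid on Visium capture areas, in which each barcoded spot collects the polyadenylated RNA of a small patch of tissue that can hold several cells. The labels list 2 capture areas for the control mouse and 2 for the mutant mouse, so each condition is represented by 1 animal.

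The deposited count matrix pools all capture areas and holds 40624119 unique molecular identifiers (UMIs) over 32285 genes and 4713 spots. Its spots carry the numbers 1 to 4, which match no sample label, and the 4 libraries are therefore reported by number without a condition. No comparison of the control mouse with the mutant mouse was made, and no value below stands for either. Library 1 had 1662 spots with at least 500 UMIs and a median of 7898.5 UMIs and 3579 genes per spot. Library 2 had 715 spots with medians of 7186 UMIs and 3382 genes, library 3 had 1296 spots with medians of 9043 UMIs and 3981 genes, and library 4 had 943 spots with medians of 9829 UMIs and 4131 genes. The summed depth was 13304973, 5223890, 12533691 and 9533952 UMIs in libraries 1 to 4. Mitochondrial transcripts made up 8.93%, 9.55%, 7.34% and 7.46% of these UMIs. There are no replicates, and the intervals given are 95% intervals for counting error only.

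Transcripts of VEGF and its receptors are given first because the study blocked VEGF, but their RNA levels do not measure that block. Flt1, which encodes VEGFR1 (ENSMUSG00000029648), was measured at 37.9 UMIs per 1000000 UMIs of the library (counts per 1000000, CPM, with an exact Poisson interval of 34.7 to 41.3) in library 1, 34.6 (29.8 to 40.1) in library 2, 24.5 (21.8 to 27.4) in library 3 and 25.3 (22.2 to 28.7) in library 4. The highest library was 1.55-fold above the lowest (1.34 to 1.79), with a median of 29.96 CPM over the 4 libraries. Whether reads of the transgene are counted under Flt1 is not given in the sources used here. Vegfa, the main ligand of VEGFR1 and VEGFR2 (ENSMUSG00000023951), lay at 53.3 CPM (49.4 to 57.4) in library 1, 53.8 (47.7 to 60.5) in library 2, 188 (181 to 196) in library 3 and 163 (155 to 171) in library 4. Its highest library was 3.53-fold above its lowest (3.25 to 3.85).

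Among the other genes of the VEGF list, the neuropilin co-receptor Nrp2 had the widest range among genes with at least 100 UMIs, at 3.76, 2.68, 27.1 and 31.9 CPM in libraries 1 to 4, a ratio of 11.9 (6.98 to 22.02). Vegfb, the member with the most UMIs over all libraries together, was measured at 195, 178, 143 and 156 CPM, below Vegfa in libraries 3 and 4. For Kdr, which encodes VEGFR2, the values of 7.52, 6.89, 9.42 and 8.08 CPM differed by less than counting error, with a ratio of 1.37 (0.934 to 2.04). The ratios of Pgf, 1.24 (0.860 to 1.82), and Vegfc, 1.15 (0.653 to 2.11), were also not distinguishable from 1 at this depth. Flt4, Vegfd and Nrp1 had 78, 66 and 43 UMIs in all. The list as a whole ranged over 0.37 log2 units between its highest and lowest library (0.12 to 0.80), at percentile 83.5 of random lists matched on expression. With every spot thinned to 2000 UMIs, Vegfa was seen in 8.54%, 11.0%, 29.8% and 22.5% of spots in libraries 1 to 4, against 31.1%, 29.7%, 66.9% and 62.1% without thinning.

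**Figure D1:**
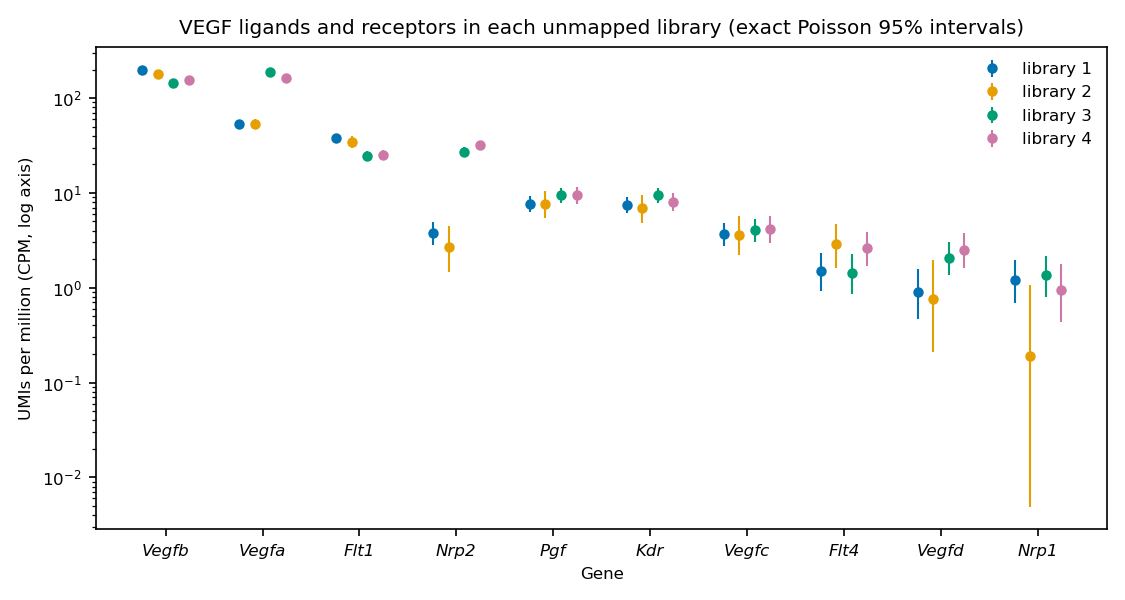
CPM (log axis) of the 10 genes of the VEGF list in each of the 4 unmapped libraries, with points for the values and bars for exact Poisson 95% intervals. Vegfa lies between 53.3 and 188 CPM and Nrp2 between 2.68 and 31.9 CPM, while the bars of Kdr, Pgf and Vegfc overlap in all 4 libraries.

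The libraries differed far more in transcripts of reactive glia, the set induced in astrocytes and other glia after injury. Serpina3n, a serine protease inhibitor of reactive astrocytes (ENSMUSG00000021091), was measured at 29.2, 31.2, 564 and 449 CPM in libraries 1 to 4. The intermediate filament gene Vim stood at 62.8, 71.6, 478 and 373 CPM, and Lcn2, which encodes a siderophore-binding lipocalin (ENSMUSG00000026822), at 0.526, 0.766, 510 and 371 CPM. All 9 members were higher in library 3 than in library 1, and the list median differed between these by 4.27 log2 units (3.85 to 4.39), above all 10000 random lists. The disease-associated microglia list spanned 2.90 log2 units (2.52 to 3.16), with its highest value in library 3 and its lowest in library 2. Its members with the most UMIs over all libraries together were Apoe, which encodes a lipid carrier, at 3372, 3169, 5748 and 5443 CPM, and the lysozyme gene Lyz2 at 26.2, 27.9, 487 and 441 CPM. The rank of Lyz2 rests on libraries 3 and 4. Clec7a of this list has no row in the matrix. The proliferation list spanned 3.56 log2 units (2.69 to 4.56), on low counts: Ccnb1 stood at 0.526, 1.15, 20.3 and 19.3 CPM and Pcna, its most abundant member, at 60.1, 60.3, 71.2 and 72.1 CPM. The interferon response list spanned 1.89 log2 units (1.16 to 2.21), with Bst2 at 8.19, 8.81, 51.1 and 38.9 CPM and Isg15 at 4.43, 4.21, 15.96 and 16.5 CPM.

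Markers of meningeal cells and red blood cells had their highest values in library 3 as well. The leptomeninges list spanned 2.03 log2 units (1.80 to 2.35), with Ptgds, which encodes prostaglandin D synthase, at 3079, 4291, 7621 and 5578 CPM and Mgp at 43.8, 71.4, 327 and 186 CPM in libraries 1 to 4. The red blood cell list spanned 1.23 log2 units (1.16 to 1.34), with the globin transcripts Hbb-bs at 450, 340, 751 and 694 CPM and Hba-a1 at 198, 145, 322 and 279 CPM. The lymphocyte list spanned 1.82 log2 units (0.72 to 4.27) on the 3 genes with at least 20 UMIs and was highest in library 4, and of these Trbc2 stood at 0.451, 0.383, 24.5 and 21.5 CPM, Ighm at 7.52, 6.89, 10.4 and 7.66 CPM and Cd79a, with 54 UMIs in all, at 0.676, 0.574, 1.60 and 2.31 CPM. Of the Trbc2 UMIs, 85.6% lay in 1 region that held 5.52% of the UMIs of 6 other T cell genes. The hypoxia response list spanned 1.05 log2 units (0.91 to 1.18), with the glycolytic genes Pgk1 at 566, 529, 693 and 626 CPM and Ldha at 220, 211, 706 and 637 CPM.

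Neuronal transcripts differed in both directions. Th, which encodes the rate-limiting enzyme of dopamine synthesis (ENSMUSG00000000214), was measured at 584, 531, 123 and 116 CPM in libraries 1 to 4, and Trh, which encodes thyrotropin-releasing hormone, at 258, 258, 51.1 and 55.7 CPM. Calb1 of the same periglomerular list went the other way, at 18.8, 19.9, 68.5 and 75.6 CPM, and the list median spanned 2.13 log2 units (1.94 to 2.26), highest in library 2 and lowest in library 3. Olfactory sensory neuron axon transcripts spanned 1.36 log2 units (1.196 to 1.63), from library 1 to library 3, with the calcium-binding S100a5 at 816, 642, 155 and 286 CPM and Gng13 at 403, 316, 314 and 402 CPM. The inhibitory transmission list spanned 1.12 log2 units (1.04 to 1.17), with Gad1, a gene of GABA synthesis, at 1345, 1398, 712 and 608 CPM and Slc32a1, which encodes the vesicular GABA transporter, at 337, 333, 177 and 161 CPM. Transcripts of forebrain excitatory neurons spanned 2.55 log2 units (2.21 to 2.84), highest in library 4 and lowest in library 2, with neurogranin (Nrgn) at 112, 151, 1182 and 1239 CPM and Camk2a at 123, 144, 298 and 294 CPM.

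The other 14 lists spanned less than 1 log2 unit. Astrocytes spanned 0.20, endothelium 0.29, mural cells 0.34, oligodendrocytes 0.42, olfactory ensheathing glia 0.56, immediate early genes 0.59, migrating neuroblasts 0.72, mitral and tufted cells 0.74, oligodendrocyte precursors 0.76, microglia 0.77, granule cells 0.79 and ependyma 0.84 log2 units. The ependyma value had an interval of -0.03 to 1.97 and was -0.11 with the regions of a library weighted alike, a setting in which oligodendrocytes spanned 1.504, olfactory ensheathing glia 1.08 and red blood cells 0.81 log2 units. Within the astrocyte list, Aldoc was measured at 989, 921, 941 and 1007 CPM and Slc1a2 at 697, 692, 813 and 923 CPM, while Gfap, the intermediate filament gene of reactive astrocytes, stood at 106, 83.7, 360 and 409 CPM. The sex-linked list spanned 0.15 log2 units, with Xist at 0 UMIs in all 4 libraries and Eif2s3y between 45.7 and 55.2 CPM.

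**Figure D2:**
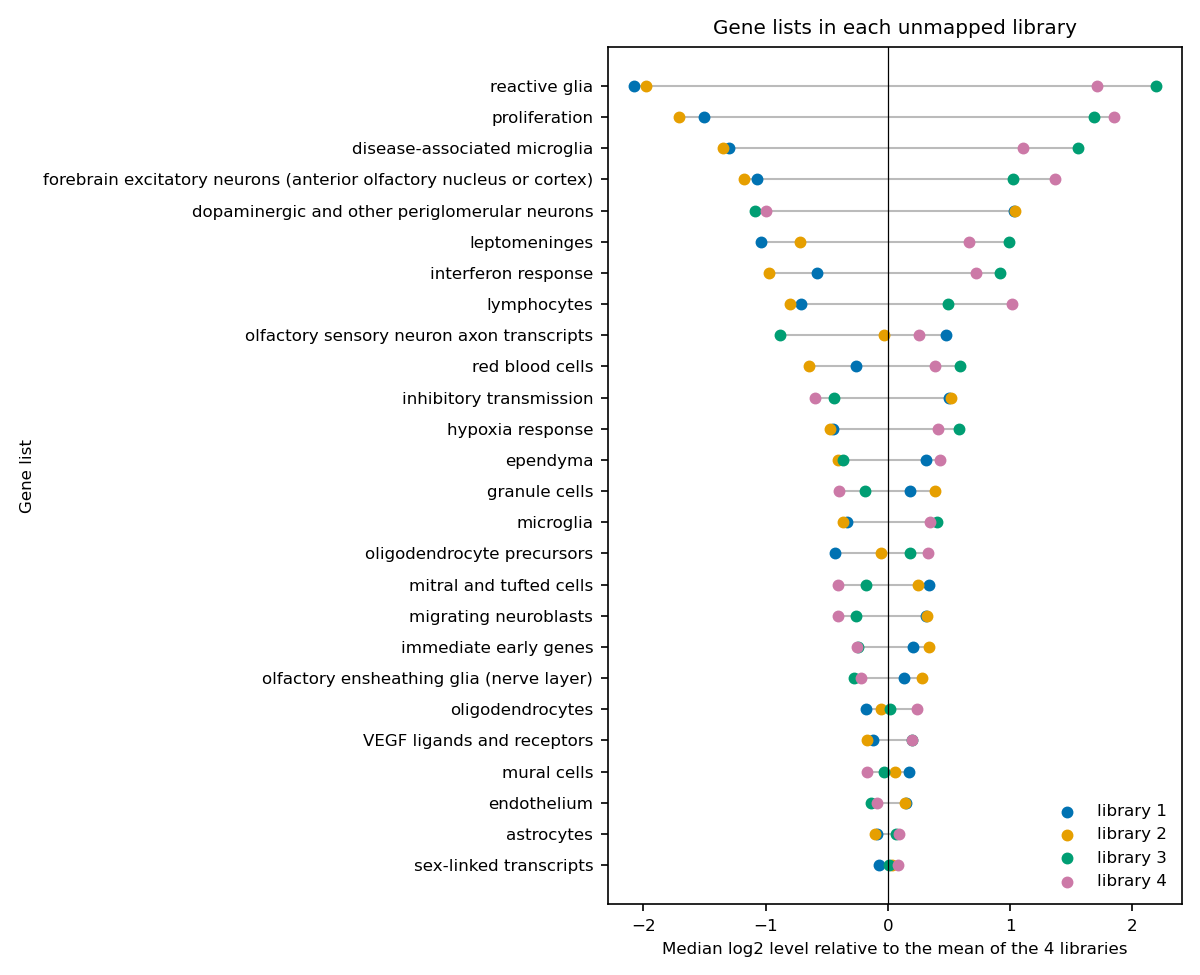
Median log2 level of each of the 26 gene lists in the 4 unmapped libraries, relative to the mean of the libraries (x axis), with 1 point per library and a grey line over their range. Reactive glia has the widest range at 4.27 log2 units and sex-linked transcripts the narrowest at 0.15.

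Over single genes, 773 of 9852 genes with at least 500 UMIs in all and 3 in each library (7.85%) had their highest library over 2-fold above their lowest. No interval was required for this count. The widest ratio was that of Lcn2, at 970 (470 to 2413), followed by the complement gene C3 at 541 (185 to 2625), which had 3 UMIs in library 1. The odorant-binding protein genes Obp1a and Obp1b followed with ratios of 306 (185 to 547) and 146 (81.4 to 293), both highest in library 1. S100a9, a calprotectin subunit of neutrophils, had a ratio of 75.7 (25.8 to 368), with 3 UMIs in library 2. The other genes among the 20 widest were Tnnc1, Itpka, Timp1, Enc1, Bpifb6, Bpifb4, Bhlhe22, Crym, Lgals3, Ces1d, Gpx6, A2m, Gnrh1, Gdpd3 and Wfdc17, with ratios between 19.4 and 37.3. Genes with fewer than 3 UMIs in a library were not ranked and can differ more widely. Trbc2, with 520 UMIs in all, is 1 of them. Unnamed gene models, mitochondrial and ribosomal protein genes were not ranked either. The count of genes was 1312 with a minimum of 200 UMIs, 471 with 1000 UMIs, 485 without library 3 and 503 without library 4.

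The spots fell into 13 regions, each named by its leading gene, and the lists differed among them. In the Bpifb9b region, olfactory sensory neuron axon transcripts lay 3.99 to 4.29 log2 units above the rest of the library in libraries 1 and 2, with S100a5 at 4760 and 3467 CPM; these transcripts are shared by the nerve layer and the nasal mucosa, which were not told apart for this region. Olfactory ensheathing glia, which wrap these axons in the nerve layer, lay 2.27 to 2.35 log2 units higher in the same spots, with Apod at 3363 and 3633 CPM and Fabp7 at 2338 and 1903 CPM. Periglomerular neuron transcripts were highest in the Gal region, 1.68 to 1.78 log2 units above the rest, with Th at 930 and 894 CPM and Trh at 435 and 459 CPM. Mitral and tufted cell transcripts were highest in the Tbx21 region, by 1.75 log2 units in library 3, the only library with at least 30 of its spots there, with Uchl1 at 1613 CPM and Cdhr1 at 1370 CPM. Migrating neuroblast transcripts were highest in the Necab2 region, 2.02 to 2.30 log2 units above the rest of libraries 3 and 4, with Dcx, a microtubule-binding protein of immature neurons, at 301 and 277 CPM. Granule cell transcripts were 1.05 to 1.27 log2 units higher there, and 0.99, 1.13, 1.45 and 1.33 log2 units higher in the Adamts19 region of libraries 1 to 4, where Pcp4 stood at 1845, 1785, 2060 and 1912 CPM.

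In the Mmp12 region of libraries 3 and 4, disease-associated microglia transcripts lay 2.72 to 3.35 log2 units above the rest, reactive glia 2.76 to 2.88, microglia 1.13 to 1.36 and the interferon response 1.55 to 2.0 log2 units. Markers of other cell types were raised in the same spots, olfactory ensheathing glia by 1.90 and 1.59 and leptomeninges by 1.04 and 1.56 log2 units in libraries 3 and 4. The interferon response also lay at 1.77 and 1.51 in the Bpifb9b region of libraries 1 and 2 and at 1.67 in the Fmod region of library 3. In the Mmp12 region, Apoe reached 17000 and 16717 CPM, Lyz2 2418 and 2299 CPM, Lcn2 1996 and 1514 CPM, and Gpnmb 794 and 594 CPM in libraries 3 and 4. In libraries 1 and 2, where this region held 2 and 0 spots, reactive glia transcripts were highest in the Bpifb9b region, by 2.16 and 2.20 log2 units. Leptomeningeal transcripts lay 2.59 to 2.66 log2 units above the rest in the Bpifb9b region of libraries 1 and 2, and 2.32 and 2.15 in the Fmod region of libraries 3 and 4. Vascular and blood lists were raised in both of these, with mural cells at 1.58 and 1.52, red blood cells at 2.63 and 1.82 and endothelium at 1.15 and 1.02 in the Bpifb9b region of libraries 1 and 2, and mural cells at 1.63 and 1.51, red blood cells at 1.63 and 1.91 and endothelium at 1.58 and 1.52 in the Fmod region of libraries 3 and 4. Forebrain excitatory transcripts lay 1.86 to 2.59 log2 units above the rest in the Trbc2 region, with Nrgn at 3530.5 and 3594 CPM. Oligodendrocyte transcripts lay 3.77 log2 units higher and those of their precursors 1.02 higher in the Mobp region of library 4, with Mbp, a major myelin protein, at 10571 CPM.

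The highest region of each list was taken as the one with the highest value in the lowest of its libraries with at least 30 spots, so that single libraries can hold higher values elsewhere. By this rule, 17 of 26 lists lay over 1 log2 unit above the rest of the library, and at or above the 99th percentile of random lists, in each library with at least 30 spots of their highest region. For 14 of these, that region had such a number of spots in at least 2 libraries. The random lists were scored in the same region and did not pick their own highest one. The percentile thus takes no account of the choice among regions. The values of the other lists in the region chosen this way were 0.56 to 0.66 for VEGF, 0.85 to 0.98 for astrocytes and 0.83 to 0.87 for hypoxia, all in the Mmp12 region. Immediate early genes had values of 0.61 to 1.07 in the Adamts19 region, inhibitory transmission 0.53 to 0.56 and sex-linked transcripts 0.62 to 1.01 in the Necab2 region, proliferation 0.60 to 0.73 in the Car9 region, lymphocytes 1.28 to 1.90 in the Fmod region and ependyma 1.15 in the Bpifb9b region of library 1. Higher values in single libraries were 0.98 for VEGF in the Fmod region of library 3, 1.97 for ependyma and 1.43 for proliferation in the Mmp12 region of library 3, and 1.15 for proliferation in the Necab2 region of library 4. Inhibitory transmission reached 1.24 and 1.33 in the Adamts19 region of libraries 3 and 4, where libraries 1 and 2 had 0.08 and -0.02. The oligodendrocyte value was 0.57 at resolution 0.4 and 0.56 with each gene centred within its library. That of their precursors was 0.43 and 0.18 in these settings and 0.90 at resolution 1.2. These settings drew new regions, so the highest region need not match the Mobp region. Without library 4 the values were 0.63 and 0.30, but in another region. The Mobp region had 32 spots in library 4 and 29 in library 3, below the minimum of 30. At resolution 0.4 the migrating neuroblast value was 0.57 and the microglia value 0.97. Without library 3 the mitral and tufted cell value was 1.11, again in another region, as the Tbx21 region had 23 spots in library 4.

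**Figure D3:**
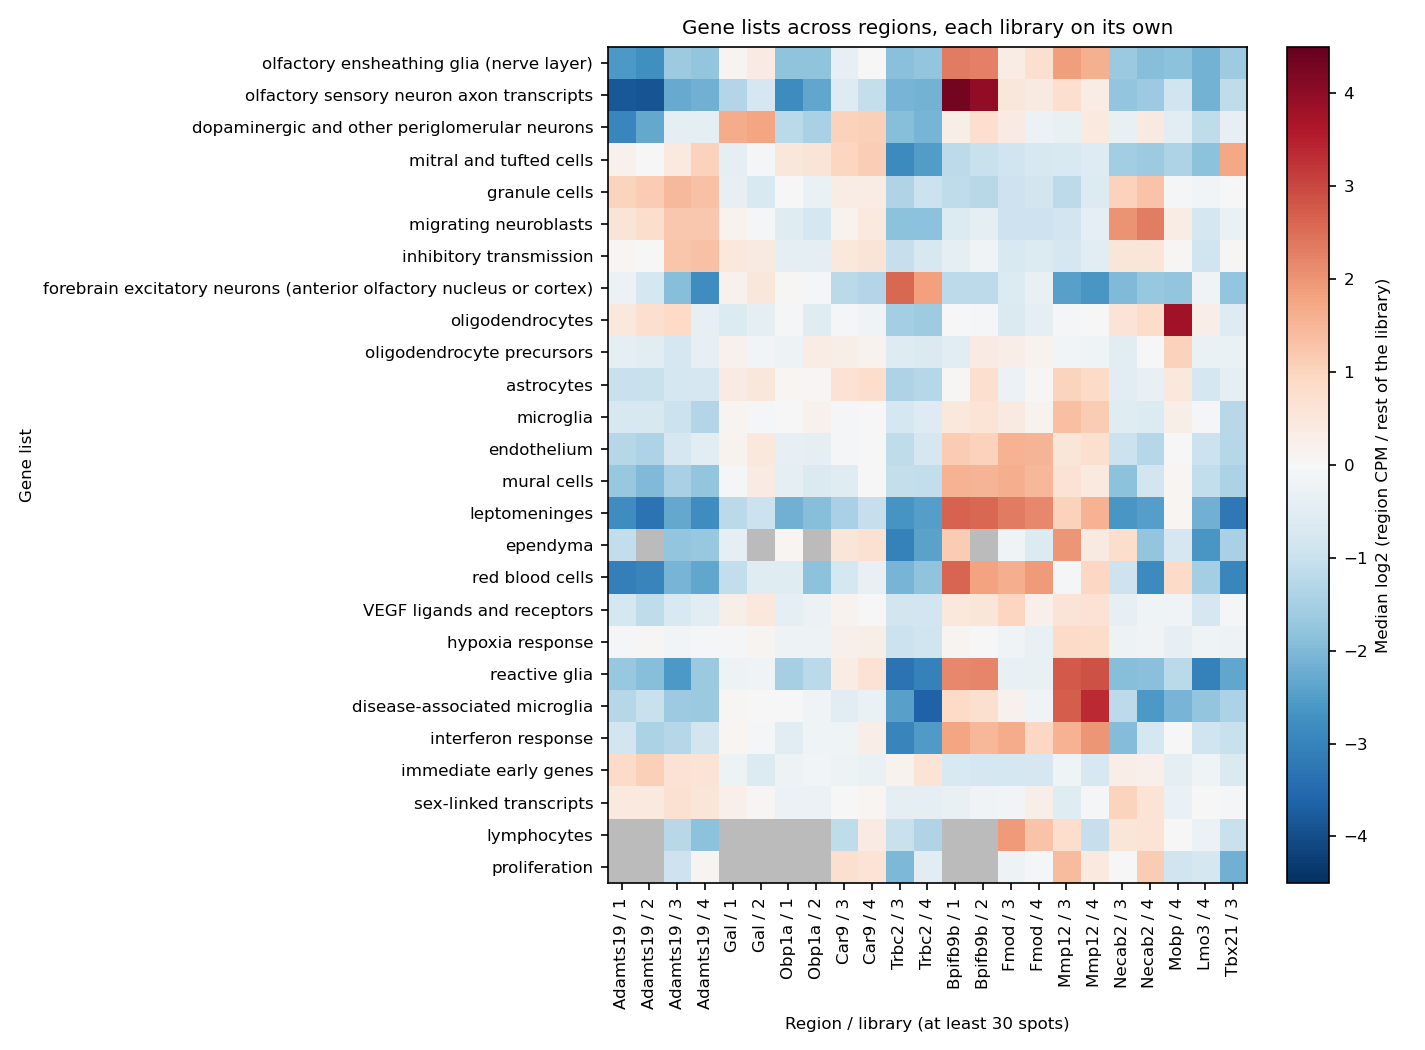
Median log2 ratio of each gene list (rows) between a region and the rest of the same library, for each region and library with at least 30 spots (columns), with red for higher, blue for lower and grey for fewer than 3 genes measured. Olfactory sensory neuron axon transcripts reach 4.29 in the Bpifb9b region, oligodendrocytes 3.77 in the Mobp region and disease-associated microglia 3.35 in the Mmp12 region.

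The libraries differed in the regions they held. The Adamts19 region made up 31.2% (exact binomial interval 29.0 to 33.5), 36.9% (33.4 to 40.6), 13.1% (11.3 to 15.1) and 9.76% (7.94 to 11.8) of the spots of libraries 1 to 4, and was the only region with at least 30 spots in each. The Gal region made up 31.4%, 29.9%, 0.849% and 0.742%, and the Bpifb9b region 14.0%, 11.0%, 0.694% and 2.12%. The Obp1a region made up 21.0%, 17.5%, 2.08% and 1.27%, although 99.9% of its Obp1a UMIs came from library 1. The Mmp12 region made up 0.120%, 0%, 13.1% and 14.1%, and the Trbc2 region 0%, 0%, 16.7% and 19.1%; a count of 0 allows up to 0.181% in library 1 and 0.420% in library 2 at 3 spots, and up to 0.222% and 0.515% by the exact binomial interval. The clustering placed no library on a common scale, so a region held mostly by some of the libraries may differ from its neighbours by library as well as by layer. At a resolution of 0.4 there were 8 regions.

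**Figure D4:**
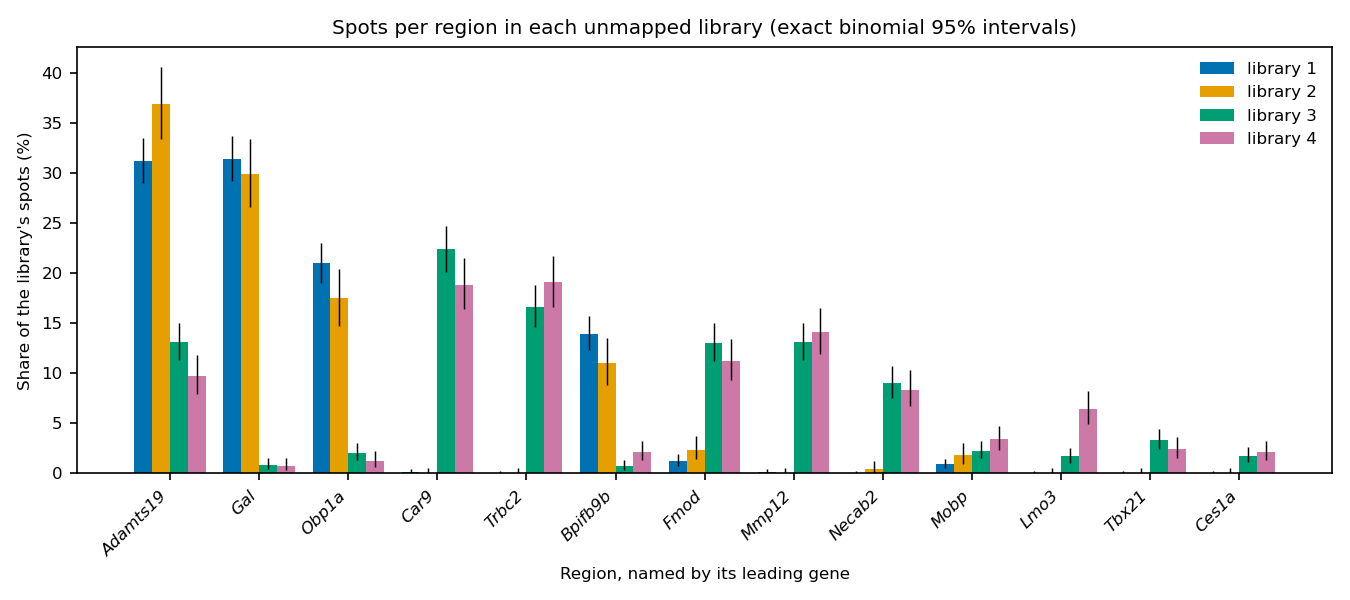
Share of each library's spots (percent) in each of the 13 regions, with 4 bars per region for the unmapped libraries and black lines for exact binomial 95% intervals. The Adamts19 region holds between 9.76% and 36.9% of the spots of every library, whereas the Trbc2 region holds 16.7% and 19.1% in libraries 3 and 4 and no spots in libraries 1 and 2.

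Levels were also set side by side within the Adamts19 region, the 1 region with at least 30 spots in every library, while 6 regions had at least 1 spot in each. It groups spots of alike expression and is not shown to be a single layer. Its spots held more UMIs on average in libraries 3 and 4 than in libraries 1 and 2, so that depth was not equal in this comparison. With each gene centred within its library, or with spots of at least 1000 UMIs, 2 regions met the minimum of 30 spots. Th, at 256, 235, 218 and 210 CPM in libraries 1 to 4, and Gad1, at 1984, 1887, 1814 and 1736 CPM, lay closer to each other there than over whole libraries. Th lay below its whole-library level in libraries 1 and 2 and above it in libraries 3 and 4. The periglomerular list had a value of -2.94 log2 units in this region against the rest of library 1. The Th values thus do not show whether the whole-library difference holds among periglomerular neurons. Other neuronal transcripts stayed apart, with Doc2g at 1256, 939, 509 and 657 CPM, S100a5 at 70.5, 55.7, 28.8 and 36.9 CPM and Enc1 at 6.86, 5.41, 33.9 and 42.6 CPM. Vegfa kept a wide range, at 47.6 (39.6 to 56.7), 51.8 (40.1 to 65.8), 197 (173 to 224) and 196 (165 to 231) CPM. Serpina3n stood at 8.0, 6.96, 164 and 206 CPM, and the complement gene C4b at 16.4, 15.5, 227 and 186 CPM. Of 23 lists with at least 3 measured genes, 4 spanned over 1 log2 unit, namely reactive glia (3.84), leptomeninges (2.33), red blood cells (1.82) and VEGF ligands and receptors (1.35). Apart from Vegfa and Vegfb, the VEGF genes had few UMIs there, with 59, 23, 16 and 11 for Flt1. The hypoxia list spanned 0.77 and inhibitory transmission 0.15 log2 units. The region had a median of 3642 UMIs per spot, below that of the other 12 regions, and simulated spots also split by depth under this clustering.

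Across spots, the lists varied together in ways shared by the 4 libraries. Of 325 pairs of lists, 9 had a Spearman rho of at least 0.3 and 3 of at most -0.3 in each library, with every spot thinned to 2000 UMIs. The score of a list sums its UMIs, so that abundant members weigh most and the other members need not share the relation. In the Adamts19 region of library 1, Apoe had 3342 UMIs against 495 for Spp1, the next of the disease-associated microglia list. Ptgds had 1408 UMIs there against 32 for Mgp, the next of the leptomeninges list. Olfactory ensheathing glia and disease-associated microglia transcripts had the highest rho when pairs are ranked by their lowest library, with 0.61, 0.60, 0.67 and 0.68 in libraries 1 to 4, followed by ensheathing glia and leptomeninges at 0.60, 0.58, 0.58 and 0.55. Single libraries held higher values, with rho of 0.32, 0.32, 0.70 and 0.63 for reactive glia with disease-associated microglia and 0.63, 0.56, 0.26 and 0.38 for ensheathing glia with sensory neuron axon transcripts. Granule cell transcripts ran against disease-associated microglia (-0.47, -0.53, -0.38 and -0.36), leptomeninges (-0.36, -0.48, -0.40 and -0.42) and ensheathing glia (-0.42, -0.46, -0.35 and -0.30). These are relations across spots of a library, which are not independent replicates. Without thinning 40 pairs met the same bounds, and within the largest region of each library none did. That region was not the same in all libraries, as the Car9 region held 290 spots of library 3 and 2 of library 1. The last count thus rests on unlike and smaller sets of spots and does not show that the relations are absent within a region.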

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

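In these paragraphs, only the ratio over 3 mucosa genes and the ratios within regions were chosen after the result was seen, while the bounds of the other tests were set after the levels per library were known and before the tested values were computed. The highest or lowest library stood apart from the other 3 in 4 of 243 values, by a gap to the nearest of them that was larger than Dixon's 95% critical value allows. For independent and normally distributed libraries, chance alone would do so in about 1 of 20 values, or 12.15 of 243. That rate need not hold here, since the libraries include capture areas of the same mouse. The tested values also share the same libraries and are not independent of each other, so no conclusion is drawn from the count. Ddx3y, a Y-linked helicase gene, stood at 38.3 CPM (34.5 to 42.4) in library 4 against 35.8, 36.0 and 36.0 CPM in libraries 1 to 3. The values of libraries 1 to 3 lie within the counting interval of library 4. Mobp, a myelin gene, stood at 224 CPM (215 to 234) in library 4 against 189, 194 and 194 CPM, which lie below that interval.

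Transcripts of nasal glands stood apart in library 1, with Obp1a at 366 CPM against 4.59, 1.197 and 1.78 CPM in libraries 2 to 4, and Obp1b at 168 CPM against 2.87, 1.28 and 1.15 CPM. Together with Mup4 and Lcn11, these genes had 8916 UMIs in library 1 and 53, 35 and 34 in the others. Free RNA spread evenly over the capture area is argued against, since the 10% of library 1 spots with the most of these UMIs held 89.3% of them. The 4 genes lead the Obp1a region, so that uneven counts across spots were already known and this test adds little. RNA spread from a local source was not tested and stays open, and 41.4% of library 1 spots held a UMI of these genes. Nasal mucosa lying on the section stays open, as the tests do not decide it: those spots had 2.22 times (2.08 to 2.37) the CPM of Omp, Cyp2g1, Cyp2a5, Bpifb9b and Stoml3 in the other spots, and 2.65 times (2.43 to 2.89) for Cyp2g1, Cyp2a5 and Bpifb9b, but 1031 of their 1205 UMIs of the 5 genes lay in the Bpifb9b region, which held 12.4% of the gland UMIs. Within the Obp1a region, which held 70.9% of the gland UMIs and where sensory neuron axon transcripts lay 2.82 and leptomeningeal transcripts 2.17 log2 units below the rest of library 1, the ratio over the 5 genes was 1.82 (1.36 to 2.43), with 57 of the 75 UMIs from Cyp2a5 at 5.36 (3.48 to 8.34), while the other 4 genes lay below 1: Omp at 0.68 (0.32 to 1.32), Cyp2g1 at 0.67 (0.20 to 1.77), Stoml3 at 0.43 (0.05 to 1.85) and Bpifb9b at 0 (0 to 2.04), each with an interval that includes 1. No biological explanation was tested, as no label ties library 1 to a mouse.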

How the results depend on the processing

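Alternatives that thin the spots before clustering, or that vary the within-region levels, were chosen after seeing the data; the others were planned. No list span over 1 log2 unit and no VEGF ratio changed direction in any alternative that was run, while the ependyma span of 0.84 became -0.11 with regions weighted alike. The 13 regions became 8 at resolution 0.4, and otherwise numbered between 10 and 19, with an adjusted Rand index to the reported regions of 0.59 to 0.72 in the other settings and 0.48 with thinned spots. Of the 1045 Adamts19 spots, 737 were deep enough to thin, and 71.2% of these shared a region after thinning, in which they made up 69.5% of the spots. Together with 1 further region, 97.7% of the 737 spots were covered. The spots of the first of these regions had a median of 4158 UMIs before thinning. The 773 genes over 2-fold apart became 1312 with a minimum of 200 UMIs and 471 with 1000 UMIs, and 485 to 649 with a library left out. The UMI minimum changes both the number of genes entered and their counting error, and the share of genes was not computed in these settings. The Vegfa ratio of 3.53 became 4.07 with regions weighted alike and 4.002 as a median over spots, and the cause was not tested. The 12 correlated list pairs became 40 without thinning and 0 within the largest region of each library, which was not the same region in all, and the cause was not tested. Lists clear of the rest of a library numbered 12 to 19 against 17, lists over 1 log2 unit apart between libraries 10 to 14 against 12, and such lists within the shared region 4 to 6 against 4. There, the reactive glia difference stayed between 3.48 and 3.93 log2 units. The Flt1 ratio stayed within its counting interval in all 6 alternatives. List values in their highest region stayed within their tolerance in 180 cases and moved in 52, and list spans between libraries in 182 and 25. The first 2 counts include the runs that left out a library, which only dropped that library's own values. The tolerance was at least the spread between the libraries of the region. Many of these cases were thus bound to stay, and the count does not measure robustness. A span was compared only where its highest and its lowest library were kept.

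No paired analysis was possible because the libraries could not be assigned to mice. The settings planned for the control-mutant comparison (each capture area left out, other scalings, other UMI minimums) were not run for the same reason. The red blood cell list has no value without haemoglobin genes. Depth limits the statements on Flt4, Vegfd, Nrp1 and other genes under 100 UMIs. Regions are partly set by depth, and within-region levels compare spots of alike expression rather than a fixed layer. Depth within the Adamts19 region was not equal between the libraries.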

Other observations

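All patterns here were noticed in the data and then tested on the same data, and the repeated thinnings of the shared region were added after the first value had been seen. The 20 genes with the widest ratios were selected for differing between the libraries, and the values of 7 of them follow. Bpifb4 was measured at 35.6, 12.1, 162 and 328 CPM in libraries 1 to 4, Bpifb6 at 17.7, 6.89, 102 and 195 CPM, and Gpx6, which encodes a glutathione peroxidase, at 18.9, 8.42, 124 and 172 CPM. Ces1d, a carboxylesterase gene, stood at 6.24, 1.91, 20.8 and 39.9 CPM. The Ces1a region, with 43 of 4616 spots and none in libraries 1 and 2, held 70.8% (69.6 to 71.9) of the Bpifb4 UMIs, 71.8% (70.2 to 73.3) of Bpifb6, 70.4% (68.9 to 71.9) of Gpx6 and 57.9% (54.2 to 61.5) of Ces1d. Without these spots Bpifb4 stood at 47.2 and 59.0 CPM and Gpx6 at 33.4 and 35.2 CPM in libraries 3 and 4. Gnrh1, which encodes gonadotropin-releasing hormone, stood at 11.0, 1.15, 23.1 and 17.3 CPM. Enc1 stood at 8.94, 8.997, 239 and 289 CPM and Itpka at 3.23, 4.21, 101 and 111 CPM.

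The 4 libraries fell into 2 clusters by overall expression. Genes over 2-fold apart numbered 14 of 9860 between libraries 1 and 2 and 9 between libraries 3 and 4, against 592 between 1 and 3, 601 between 1 and 4, 548 between 2 and 3 and 574 between 2 and 4. Different depth is argued against as the whole cause. At equal depth and equal spots the lowest of these 4 counts was 361 against 69 and 35, of 8306 genes with at least 100 UMIs. The haemoglobin genes and the spots of 4 regions led by nasal or meningeal genes are together argued against as well. Without them the lowest count was 480 against 7 and 0, of 8960 genes. Nasal and meningeal transcripts in the kept spots were not removed, so their part stays open. The leptomeninges list spanned 2.33 log2 units within the kept Adamts19 region. Different shares of regions remain open and cannot be told apart from other causes. Within the shared Adamts19 region the lowest count was 90 against 28 and 24, of 6087 genes with at least 100 UMIs. Over 20 thinnings it was 2.27 to 3.69 times the higher count of libraries 1 and 2 or 3 and 4, on both sides of the bound of 3 set for it. A difference between the mice also stays open and untested, because no label ties a library to a mouse or says which libraries share one.

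Trbc2, which encodes a constant part of the T cell receptor, had 85.6% (82.3 to 88.5) of its 520 UMIs in the region it leads, which held 8.58% of the spots. T cells in the tissue are argued against as the source, since 5.52% (2.56 to 10.2) of the 163 UMIs of Cd3e, Cd3d, Cd3g, Cd2, Lck and Cd28 lay there. The levels of the most abundant of these were 80 UMIs for Lck and 28 for Cd28 over all libraries. Other sources of Trbc2 transcripts, neurons of that region among them, were not tested and stay open.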
